A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

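BrdU incorporation was measured in synchronous cultures of the fission yeast Schizosaccharomyces pombe on 2 two-colour Agilent tiling arrays, 1 for a strain called wild-type and 1 for sap1-1. Per the labels, both strains carry the cdc10-v50 allele together with modules for uptake and phosphorylation of thymidine analogues, were held at 35 °C for 4 h, and were released at 26 °C into 10 mM hydroxyurea with 200 µM BrdU. Hydroxyurea starves cells of deoxynucleotides, so that BrdU marks DNA made near the origins that fired. Sodium azide (0.1%) stopped the cultures, per the labels. Sheared DNA was immunoprecipitated with an antibody to BrdU and amplified by random-primed PCR. Immunoprecipitated DNA carried Cy5 and whole-cell extract DNA, the input, carried Cy3 on each array, per the labels.

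Per the file headers, Agilent Feature Extraction 10.7.3.1 measured the spots, subtracted background with spatial detrending and scaled each dye by 1 linear factor per array, with no lowess curve. The deposited processed signals are intensity values on a linear scale, 1 per spot and channel. The deposited log ratio is the log10 of processed Cy5 over processed Cy3 intensity, and for non-control spots it equalled that ratio to within 3.91e-07 on either array. The deposited median spot and background signals are intensity values before any correction, per the file headers, and were used for alternatives only. The genome build behind the tile names is not given in the sources used here. Both arrays lay on 1 slide, per the file headers. Each strain has 1 array, so culture, immunoprecipitation and array cannot be told apart from strain.

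Each array held 42968 spots, of which 41551 were not controls. No probe was printed more than once. Spots marked as non-uniform or as population outliers on either array (12) were left out. Of the probes, 41251 were chromosome tiles and 300 were named for the mitochondrial genome, the mating-type region or plasmids, and these 300 were kept apart. This left 41240 chromosome tiles at a median spacing of 300 bp. The log ratio was converted to log2 and centred on the median of each array. No loess or quantile step was applied, since a large part of the genome carried signal. Median signals of all non-control probes were 1059 (Cy3) and 920.4 (Cy5) on the wild-type array and 916 and 878 on the sap1-1 array. In Cy3 1 probe, and in Cy5 6 (wild-type) or 34 (sap1-1) probes, were not well above background, and no spot was saturated.

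Tile names hold a chromosome and a position, which is the coordinate printed here, with each tile running over 300 bp. Gene names came from the NCBI reference ASM294v3, whose numbering differs from that of the tiles. The offset of each chromosome arm was found by sliding the GC content of the reference along the input signal, which depends on GC. One offset per arm, between -1800 and 4350 bp, gave correlations of 0.548 to 0.589, against 0.0190 or less in the median over other offsets, and every 300 kb block of an arm gave the same offset to within 1 tile. On simulated offsets 12 of 12 were found. The offsets were used to tell which genes lie at or next to a tile, to within about 1 tile. They were also used to place the classes taken from the reference, and to give each tile its GC content and its share of repeated sequence. No coordinate of the reference is printed. The last tile of the right arm of chromosome II lies 30.8 kb before the end of the reference, so tlh2 has no tile, and distances from an end are counted from the last tile.

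Ratios were smoothed by averaging tiles within 500 bp either side. A BrdU-enriched region was a run of at least 3 tiles with a smoothed value of at least 1 (2-fold above the median of the array), and runs under 1000 bp apart were merged. Regions of the 2 arrays were called shared with any overlap. Over the union of both sets, the mean of sap1-1 minus wild-type was counted as higher or lower from 1 log2 upwards. Mean profiles 20 kb either side of wild-type summits were compared at 50% of their height over the level 15 to 20 kb away. Classes were the outer 100 kb of the chromosomes without rDNA, the rDNA, pericentromeres (the longest interval of each chromosome with no protein-coding gene in the reference), the mating-type region (mat1 to mat3, since mat2 has no entry in the reference), and tRNA, 5S rRNA, ribosomal protein, histone, snRNA and snoRNA genes, LTRs and Tf2 elements with 1000 bp either side. The median difference of a class was placed among 10000 random sets of as many tiles, matched on the mean of both arrays in 10 bins, as a description of these 2 arrays. Intervals (95%) of medians come from resampling blocks of 10 kb 2000 times, or 300 times for the coding, intergenic and arm classes, and cover tile scatter only. Input was the log2 processed Cy3 signal centred on its median. Segments of altered input were runs with a 5-tile running median of at least 0.75 in size. A tile counted as repeated where at least 10% of its 30-base words, in the matched reference sequence, occur more than once in the genome, since no probe sequences were used here.

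The rule for the regions and genes named, fixed before the data were examined, took the 10 wild-type regions with the highest smoothed summit, the 10 union regions of at least 5 tiles with the most negative and the 10 with the most positive difference, and a list of loci (ars1 next to hus5, the origins next to ura4, sap1, cdc10, taz1, tlh1, the mating-type region, rDNA, the promoters of the labelling modules, marker genes, histone genes and 5 meiotic genes). Alternatives were another background correction, centring, loess or quantile normalization, filters on dim or repeated tiles, and other smoothing widths, thresholds, overlaps, flanks and class lengths. The 12 kb limit for long regions, the overlap on the arms alone, the GC-corrected medians of coding and intergenic tiles and the limit of the histone class to 9 core genes (a first value had included the H2A.Z variant) were chosen after the data had been seen. So were further alternatives, namely smoothing over 2500 bp either side, a correction for GC content in 50 bins, the Cy5 signal over the mean input of both arrays, and division of sap1-1 by the slope of the broad profiles. The plan named mean spot signals for the alternatives on background, and median signals were used in their place. With 1 array per strain no test between strains was run.

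Region calling and differences were tested on simulated data built on the 41240 real tile positions with the real scatter of each array. Of 20 simulated regions of 20 tiles lowered by 1.5 log2, 100% were called 2-fold lower, and of 20 of 7 tiles, 70.0%. Before the change these regions lay well above the calling threshold, on a flat background. Simulated arrays with no difference shared the mean of both running medians over 33 tiles, and the rest of each array was moved around the genome. Since this unties short-range structure that the arrays share and leaves no broad difference by construction, these simulations, added after the data had been seen, were not used as a measure of chance for differences. Their region lengths, counts of 2-fold regions and most extreme differences are given. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for normexp (offset 50) and loess.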

Results

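Nascent DNA made in the presence of hydroxyurea was mapped by BrdU immunoprecipitation in fission yeast, to compare replication activity in a strain wild-type for sap1 with that in sap1-1. Sap1 is an essential DNA-binding protein known to bind the mating-type locus, the rDNA and LTRs. Cdc10, whose cdc10-v50 allele both strains carried, is part of the G1/S transcription factor and served to synchronise the cultures. There were 2 arrays, 1 per strain, so no value below has a replicate, and every SD, SE or interval covers the scatter of tiles within these arrays only. Each array gave 41240 usable tiles over 12539.7 kb of tiled chromosome. The 2 arrays had similar signal but not the same smoothness, since the difference between neighbouring tiles had an SD of 0.60 (log2) in wild-type and 1.02 in sap1-1. This roughness lay in short stretches, as the SD of 10 kb running medians was 1.06 in wild-type and 0.92 in sap1-1.

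In wild-type, BrdU was concentrated in 472 regions that made up 24.4% of the tiled length (3057 kb). In sap1-1 there were 681 regions over 19.5% of that length (2449.5 kb). The highest wild-type summit, at a smoothed log2 ratio of 4.36, lay in the mating-type region of chromosome II (region 2099400 to 2147999, summit tile 2133600). It fell between rpp202 and mat3-Mi in the reference, which has no entry for mat2, and sap1-1 reached 4.35 there. The pericentromeres came next, with summits of 4.26 on chromosome III (1053600 to 1147499, between 2 tRNA genes), 4.14 on chromosome II (1584900 to 1661099) and 3.95 on chromosome I (3747600 to 3791699). The right end of chromosome I (5489400 to 5574899) reached 3.82 between SPAC750.06c and SPAC750.07c, and the left end of chromosome II (300 to 47699) reached 3.51 between SPBC1348.15 and SPBC1348.01. The remaining 4 of the 10 highest summits lay on chromosome arms next to apc5 (a subunit of the anaphase-promoting complex; chromosome I, 3397500 to 3416999, 3.72), at duo1 beside rum1, the gene of a CDK inhibitor (chromosome II, 2783100 to 2807399, 3.62), between coq11 and lsm8 (chromosome III, 2267700 to 2286899, 3.55) and between nup60 and trs130 (chromosome III, 1816200 to 1828799, 3.50). All 10 of these regions were also called in sap1-1.

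**Figure D1:**
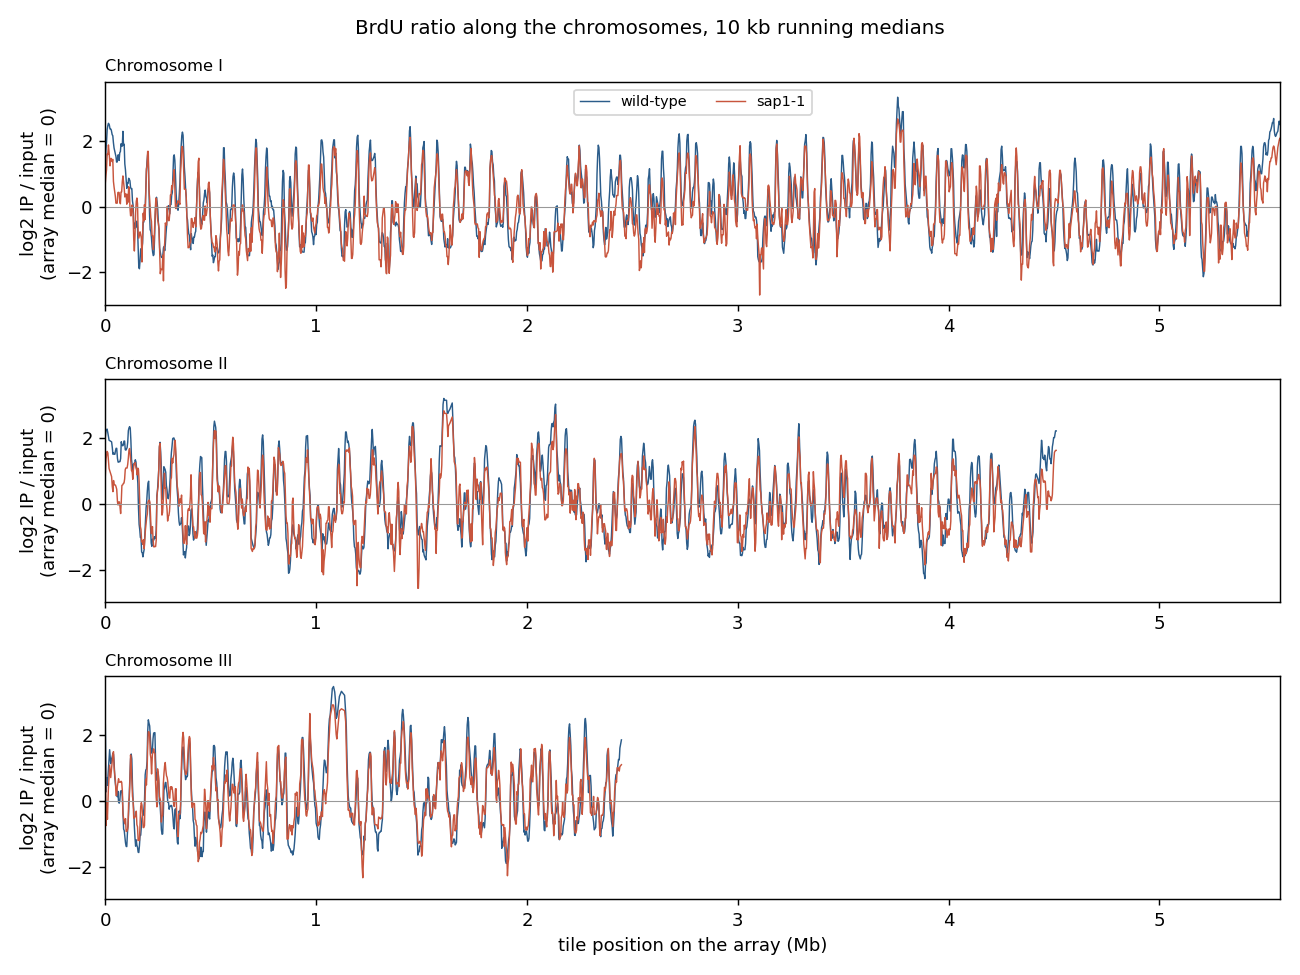
Running medians over 10 kb of the log2 ratio of BrdU immunoprecipitate to input (y axis, median of each array at 0) against tile position in Mb (x axis) for the wild-type array (blue) and the sap1-1 array (red) on the 3 chromosomes. Peaks coincide along the arms, while the blue line runs above the red line at the 4 ends of chromosomes I and II.

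Beside the small rDNA class (71 tiles, -0.95), the largest difference of a domain between the strains was at the ends of chromosomes I and II. Over the outer 100 kb of these 4 arms (1229 tiles) the median log2 ratio was 1.77 in wild-type and 0.81 in sap1-1, a median difference of -0.94 (95% interval -1.04 to -0.84), with 93.7% of tiles lower in sap1-1. Every end took part, with medians of -1.03 at the left and -0.73 at the right end of chromosome I, and -1.08 at the left and -0.89 at the right end of chromosome II. All 20 of the 20 kb bins within 100 kb of these ends were lower in sap1-1, by medians between -0.52 and -1.49. The first 20 kb, which at the left end of chromosome I hold the telomeric helicase gene tlh1, differed by a median of -0.73 over the 4 bins, and the 12 bins from 20 to 80 kb by -1.06. The 19 tiles of tlh1 differed by -0.58 ± 0.09 (SE over tiles). From 100 to 200 kb inwards, 13 of 20 bins were lower, with a median of -0.24. The median difference at these ends fell below all 10000 matched random sets of tiles, which reached from -0.15 to -0.05 (95% of sets), and it lay at percentile 0.0900 when the same positions were shifted together around the genome. Chromosome arms outside the named domains differed by -0.092, and arm windows of 20 kb with a wild-type median of at least 1 (101 windows) differed by -0.33. Centring on the mode in place of the median would move the centre by -0.61 in wild-type and 0.07 in sap1-1, which takes the difference at these ends to -1.62. Relative to the arms, which is free of the centring, the difference at these ends was -0.85.

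The ends of chromosome III, which carry the rDNA, did not show such a difference over their outer 100 kb. Their medians were 0.35 in wild-type and 0.49 in sap1-1 on the left, and 0.31 and 0.45 on the right, giving differences of 0.14 (interval -0.16 to 0.47) and 0.13 (0.05 to 0.24). With centring on the mode both became -0.54, and over the outer 50 kb the left end gave -0.25 and the right 0.054. The outermost 20 kb bin with tiles was lower in sap1-1 at each of these ends, by -0.33 ± 0.07 (SE over tiles) at 20 to 40 kb on the left and by -0.51 ± 0.09 at 0 to 20 kb on the right, and the other 7 bins were higher, by up to 0.50. In wild-type these outermost bins stood at 1.43 (left) and 1.54 (right), and the other 7 at 0.87 or less. Most of these ends thus carried less BrdU in wild-type than those of chromosomes I and II, and the contrast was not adjusted for this. In the rDNA itself (71 tiles) the ratio was lower in sap1-1 by -0.95 (-0.98 to -0.87). The input signal there was 0.30 higher in sap1-1, and the difference was -0.57 when both arrays were set against their mean input and -1.63 with centring on the mode.

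Heterochromatic regions inside the chromosomes stayed strongly labelled in both strains. Pericentromeres had a median ratio of 2.96 in wild-type and 2.55 in sap1-1, a difference of -0.49 (-0.56 to -0.41) that ranged from -0.40 on chromosome II to -0.57 on chromosome I. The mating-type region differed by -0.55 (-0.69 to -0.22). Both values were below all 10000 matched random sets, but among shifted positions they lay at percentiles 2.90 and 11.8. Division of sap1-1 by the slope of the broad profiles moved these differences to -0.031 and -0.19, while the ends of chromosomes I and II stayed at -0.78. The pericentromeres gave -0.31 without repeated sequence, -0.25 with Cy5 over the mean input of both arrays and -1.17 with centring on the mode.

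**Figure D2:**
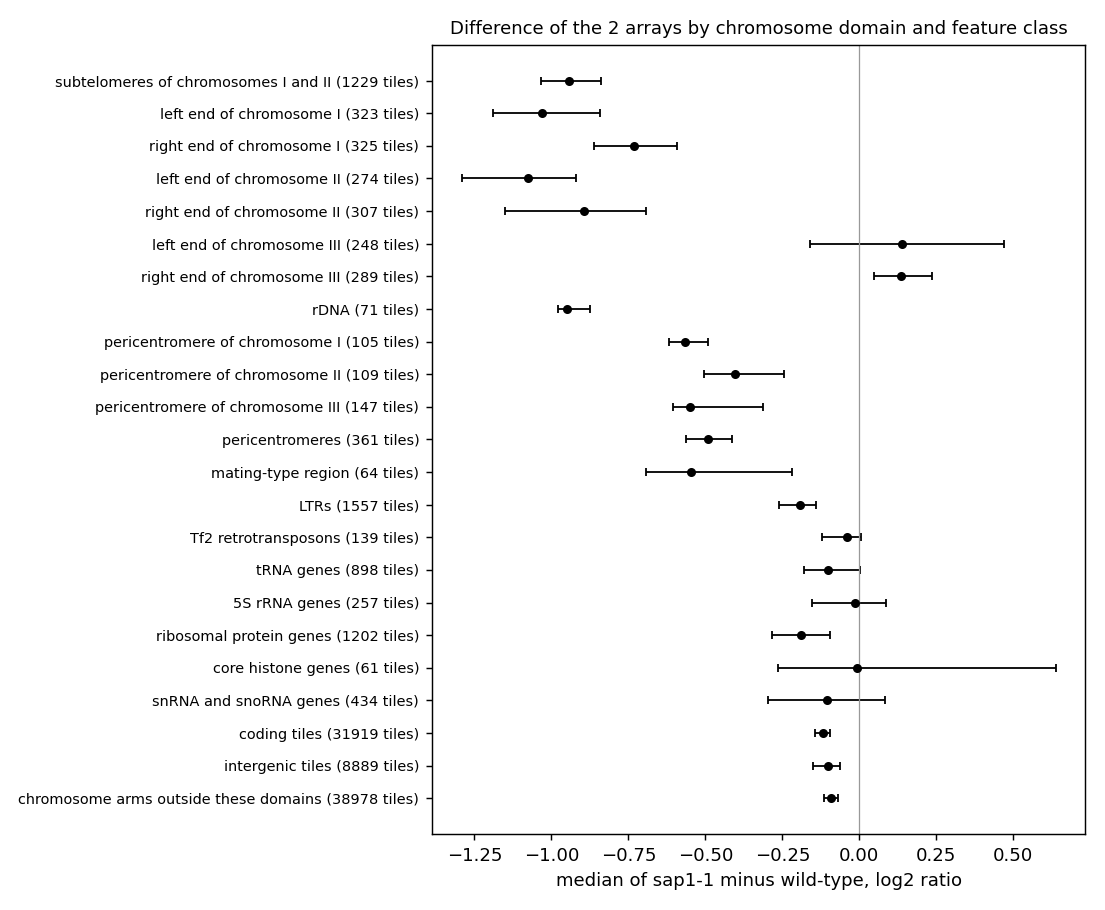
Median difference of the log2 ratio, sap1-1 minus wild-type (x axis), for each chromosome domain and feature class (y axis, with the number of tiles), where bars are 95% intervals from resampling 10 kb blocks of tiles. The ends of chromosomes I and II and the rDNA lie between -0.73 and -1.08, and classes of genes and repeats, taken over the whole genome, lie between -0.19 and -0.0072.

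Gene and repeat classes differed little between the strains. They were taken over the whole genome, so members near chromosome ends or in pericentromeres were included, and their part in the differences was not separated. tRNA genes carried BrdU above the median of the array in both (1.25 in wild-type and 1.14 in sap1-1), as did tiles at Tf2 retrotransposons (1.10 and 1.07), 5S rRNA genes (0.78 and 0.82) and LTRs, which Sap1 is known to bind (0.69 and 0.45). Their median differences were -0.10, -0.040, -0.015 and -0.19, and those of the first 3 classes changed sign under between-array quantile scaling, loess or division by the slope. The LTRs (238 elements) lay below all matched random sets but at percentile 7.13 among shifted positions. Ribosomal protein genes (138 genes) differed by -0.19, at percentiles 0.120 and 10.1, and snRNA and snoRNA genes by -0.10. The 9 core histone genes differed by -0.0072 with their flanks, a value of either sign across alternatives. Intergenic tiles had higher ratios than coding tiles in both strains, with medians of 0.70 against -0.18 in wild-type and 0.64 against -0.19 in sap1-1. Ratios fell with GC content, and after correction for it these medians were 0.27 against -0.087 and 0.22 against -0.074. Among the histone genes, the divergent pair hta1 and htb1, for H2A and H2B, had ratios of 2.67 and 2.60 in wild-type and 2.46 and 2.48 in sap1-1, while the 6 genes for H3 and H4 lay between -2.03 and -1.19 in wild-type and between -2.56 and -0.54 in sap1-1.

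Most regions were called in both strains. Of the wild-type regions 361 of 472 (76.5%) overlapped a sap1-1 region, and 502 of 681 sap1-1 regions (73.7%) overlapped a wild-type region. Among regions of at least 5 kb the numbers were 180 of 186 and 140 of 141. On the arms alone 328 of 434 wild-type regions and 440 of 615 sap1-1 regions were shared, and 157 of 163 and 126 of 127 of those of at least 5 kb. Regions seen in 1 strain were short and low, with median lengths of 1.2 kb and median heights of 1.43 for the 111 in wild-type, and 0.9 kb and 1.57 for the 179 in sap1-1. With centring on the mode the observed shares were 56.1% and 95.4%.

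By the 2-fold rule, 41 of 638 union regions were lower and 75 higher in sap1-1. These counts depend on where the arrays are centred, with 223 lower and 7 higher after centring on the mode. Of the 75 higher regions, 72 were called in sap1-1 alone, where the median length of such regions was 0.9 kb. Of the 41 lower regions, 31 were called in wild-type alone, where it was 1.2 kb. Simulated arrays with no difference gave medians of 101.5 lower and 248 higher regions over 20 runs, more than were observed. Untying the short-range structure that the arrays share can raise such counts, so they do not measure chance here. Among the 85 regions of at least 12 kb, a limit chosen after the data had been seen, 6 were 2-fold lower in sap1-1 and 0 higher. Of all 638 union regions 332 were below 0 (median -0.041), and of the 597 on the arms 300 (median -0.0015). Regions ran longer on the smoother wild-type array, so a limit on length can favour places that are high in wild-type. Of the 85 long regions 78 were below 0 (median -0.40), among them 65 of 72 on the arms (median -0.37) and the 6 that were 2-fold lower. Of these 6, 5 lay in the subtelomeres, namely at the left end of chromosome I (69300 to 96599, between ght3 and shu1, -1.33 ± 0.08 SE over tiles), the left end of chromosome II (59700 to 84899, at the L-asparaginase gene SPBPB21E7.09, -1.38 ± 0.11, and 86100 to 99299, -1.12 ± 0.11, where the input differed by -0.58), and the right end of chromosome II (4463100 to 4487399, between SPBPB2B2.05 and SPBPB2B2.06c, -1.41 ± 0.09, and 4489200 to 4510799, -1.02 ± 0.07). The other was on chromosome I (2332200 to 2345399) with its summit at mug68, between neo1 and nas6, where the mean was 1.65 in wild-type and 0.22 in sap1-1, a difference of -1.44 ± 0.13. With within-array loess the regions I 69300 (-0.91), II 59700 (-0.91) and II 4463100 (-0.95) were under 2-fold.

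The other regions with the most negative differences were arm regions called in wild-type alone, 2 of them 6.0 and 5.7 kb long and 4 of 1.5 to 2.1 kb. They lay at jmj1 on chromosome I (2528100 to 2529599, 5 tiles, -2.07 ± 0.34), at seh1 and nxt2 on chromosome I (2397000 to 2402999, 20 tiles, -1.61 ± 0.27), at cnb1 and psi1 on chromosome III (2193300, -1.58), at a phenylalanine tRNA gene on chromosome II (2576700, -1.47), between csk1 and pis1 on chromosome I (647700 to 653399, 19 tiles, -1.39 ± 0.18) and at tho5 on chromosome II (757200, -1.34). With within-array loess I 647700 gave -0.92. The most positive difference was at the hexose transporter gene ght4 on chromosome II (156300 to 158399, 7 tiles), where the mean was -0.75 in wild-type and 1.40 in sap1-1, a difference of 2.16 ± 0.14. A second region between ght4 and frp1 (159600 to 161099) differed by 1.42. The other 8 were 1.5 to 2.1 kb long and differed by 1.17 to 1.51. With centring on the mode these 8 (from 0.49 at II 541200 to 0.83 at III 760800) and the second ght4 region (0.74 at II 159600) were under 2-fold. They lay at oca2, next to ago1 (the argonaute gene), beside ser3 and between ubp11 and pat1, at ppk1, at SPAC4H3.17, at hsr1, and between uvi15 and cut12. Regions this short are less surely measured, as 85.0% of simulated 7-tile regions with no change were called and stayed under 2-fold, and the differences found ran from -2.11 to 1.03. Those simulated regions lay well above the threshold on a flat background and were not picked as extremes. The share may thus be too favourable for the regions named here. In the simulated arrays with no difference, the most negative difference of a region of at least 5 tiles had a median of -2.96 over 20 runs (-3.40 to -2.06). The most positive had a median of 2.86 (2.54 to 3.58). As with the counts, untying short-range structure can raise these values, so they do not measure chance here.

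Regions called on each array by itself, all above the same threshold, had similar summits. The median summit was 1.90 in wild-type and 1.88 in sap1-1. The mean over the 348 union regions called in both strains differed by a median of -0.17. The median length was 2.7 kb (quartiles 1.2 and 8.7) in wild-type and 1.8 kb (1.2 and 4.2) in sap1-1, and 1.8 and 1.5 kb with within-array loess. Simulated arrays shared 1 broad profile and had the scatter of each array. Their median lengths were 2.1 kb (1.8 to 2.7 over 20 runs) for wild-type and 1.8 kb (1.8 to 2.1) for sap1-1. Scatter alone thus gave shorter regions in sap1-1 in the median of the runs, but by less than observed. The observed 2.7 kb of wild-type equalled the highest of the runs. As these simulations untie short-range structure that the arrays share, they do not tell how much of the observed difference in length comes from scatter. Around wild-type summits the mean profile was a narrow spike on a broad shoulder. Within 1 kb of the summit it averaged 1.55 in wild-type and 1.28 in sap1-1, and 3 to 6 kb away 0.84 and 0.50. These summits were picked on the wild-type array, and around sap1-1 summits the averages within 1 kb were 1.32 in wild-type and 1.37 in sap1-1, and 3 to 6 kb away 0.77 and 0.50. At 50% of the height its width was 9.3 kb in wild-type and 3.0 kb in sap1-1, but that level falls on the edge of the shoulder, and the sap1-1 width was 9.9 kb after correction for GC content. Around summits of regions of at least 5 kb the widths were 10.5 and 8.1 kb.

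Across tiles of the 2 arrays Pearson's r was 0.743 and Spearman's rho 0.737, as a description across tiles, which are not independent. Smoothing raised r to 0.804 and 10 kb running medians to 0.901. The total-least-squares slope of sap1-1 on wild-type was 1.15 for single tiles and 0.850 for running medians, so the broad profile had a smaller range in sap1-1 while single tiles had a larger one. Across the 638 union regions r was -0.0599, with 348 of them called in both strains. A union region had to pass the threshold on at least 1 array. Places low on both arrays are thereby left out, which lowers r by selection, so this value does not measure how alike the strains are.

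The 27 loci chosen in advance that had tiles differed by between -1.51 and 0.85, with 17 of them lower in sap1-1. At hus5, next to the early origin ars1, the ratio was 1.75 ± 0.13 in wild-type and 1.82 ± 0.14 in sap1-1 (SD over 4 tiles). Within 5 kb of ura4, beside the ars3002 cluster, the highest smoothed value was 2.08 in wild-type and 1.83 in sap1-1. The telomere-binding protein gene taz1 and cdc10 carried little BrdU in both, at -1.82 in wild-type and -0.96 in sap1-1 for taz1, and at -1.56 in wild-type with a difference of 0.56 ± 0.39 (SE over 11 tiles) for cdc10. Of these loci 3 differed by at least 1, all lower in sap1-1, namely arg3 (-1.51 ± 0.41, SE over 5 tiles), mcp7 (-1.22 ± 0.56) and leu1 (-1.17 ± 0.32). The value of mcp7 was -0.33 with within-array loess, -0.74 with no background subtraction and -0.77 with normexp, and that of leu1 -0.72 with quantile scaling and -0.89 with loess, all under the 2-fold limit. Just under that limit were hht2 (-0.99 ± 0.15, but -0.32 with within-array loess) and his7 (-0.99 ± 0.53). Of the 5 meiotic genes only mcp7 passed it, and the others differed by -0.42 ± 0.11 (mei4), -0.13 ± 0.16 (mug8), 0.070 ± 0.11 (ssm4) and 0.22 ± 0.32 (mug9). The genes whose promoters drive the labelling modules, nmt1 and adh1, differed by -0.92 ± 0.13 and -0.52 ± 0.17.

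The whole-cell extract channel showed whether copy number differed between the strains. Input signals of the 2 arrays correlated at 0.986 across tiles, and 97.7% of tiles differed by at most 0.5. Input was 2-fold lower in sap1-1 at 21 tiles and 2-fold higher at 19. Of sap1 itself, 7 tiles were measured, and their BrdU ratio was 0.41 ± 0.57 in wild-type and 0.10 ± 0.98 in sap1-1 (SD over tiles). The input at 1 of these tiles (chromosome III, 562200 to 562499) was lower in sap1-1 by -1.35, and the other 6 lay between -0.43 and 0.35. The longest stretch of altered input was on the left arm of chromosome II (92700 to 102899, 27 tiles), at -1.09, across 4 neighbouring transporter genes from SPBPB10D8.04c to SPBPB10D8.07c. Input was higher in sap1-1 at rDNA tiles at both ends of chromosome III, by 0.94 at 3300 to 4799, 0.78 at 13500 to 14999 and 0.80 at 2448900 to 2450399. At the 7 marker genes ura4, leu1, ade6, his3, his7, lys1 and arg3, the input differed by -0.11 to 0.10.

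**Figure D3:**
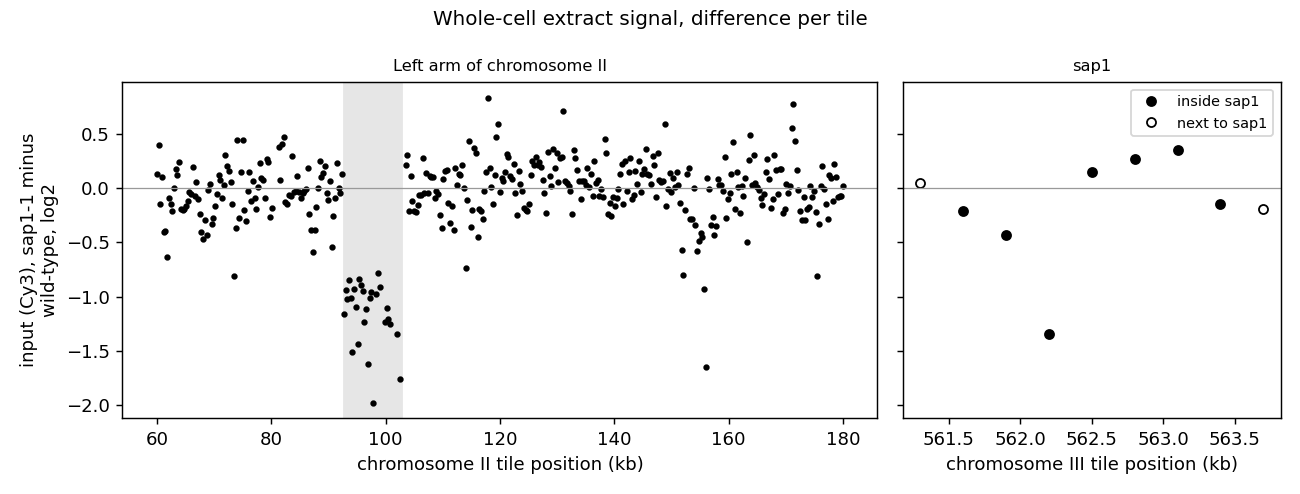
Difference of the log2 input (Cy3) signal, sap1-1 minus wild-type (y axis), per tile against tile position in kb (x axis) on the left arm of chromosome II and at sap1 on chromosome III. The 27 tiles in the shaded segment have a median of -1.09, and 1 tile inside sap1 lies at -1.35.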

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

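Of the tests in this part, all except that of the place of the spots on the slide were chosen after the result they bear on had been seen.

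BrdU was lower at the ends of chromosomes I and II in sap1-1, by a median of -0.94. A weaker profile over the whole array would leave little of this after division by the slope of the broad profiles, but -0.78 remained (95% interval -0.91 to -0.65). More input at these ends is argued against by a median input difference of 0.022, and sequence shared with other places by a difference of -1.01 on the 844 tiles whose sequence occurs once. An effect of sap1-1 on replication of these ends may account for the pattern, as a hypothesis drawn from these 2 arrays that was not itself tested. A difference between the cultures or the immunoprecipitations, such as release from the arrest, cannot be told apart from the strain, since each strain has 1 array.

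A signal outside the main comparison was the lower input of the sap1-1 array on the left arm of chromosome II, at -1.09 over 27 tiles (92700 to 102899). A blemish would put the spots close together on the slide, but the median distance between them lay at percentile 77.6 of random sets. An effect on Cy3 alone would leave Cy5 level with its flanks, but Cy5 lay below them by a further -0.51 (-0.76 to -0.26). Fewer copies of these neighbouring, similar transporter genes in the sap1-1 strain could account for the lower input. For this, 100% of the tiles hold sequence found more than once within the segment, a value partly known beforehand. Fewer copies alone would lower Cy5 about as much as input, but -1.09 lies outside the interval of the Cy5 difference to the flanks. That comparison takes the BrdU change of the segment to equal that of its flanks, which was not tested. Not set against each other, Cy5 was lower by a median of -1.44 in the segment and -0.93 in the flanks. Whether fewer copies alone account for both channels thus cannot be told. A difference in the background of the strains unrelated to sap1-1 stays open.

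Input was also lower at 1 tile inside sap1 (chromosome III, 562200 to 562499), by -1.35, with Cy5 lower by -1.85. A probe that is dim on any array is argued against by its place at percentile 72.8 of the wild-type input. That place cannot tell of a poor spot on the sap1-1 array alone, where the centred input of the tile was -0.68. Drops of both channels by over 1 at a tile whose neighbours were within 0.5 in input occurred at 2 tiles in the genome, and 1 of these was this tile. The neighbours were not level in Cy5, which was lower by -2.03 at the adjacent tile (561900 to 562199). With input 2-fold lower at only 21 tiles in all, such a count could not have been large, so a sequence change of the sap1-1 allele under this probe stays untested.

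Input on the sap1-1 array was higher at 4 places on chromosome III, all of repeated sequence. The differences were 0.94 at 3300, 0.78 at 13500 and 0.80 at 2448900, near the ends, and 0.57 at 1082100, within the pericentromere. The place at 1082100 held only 2 tiles, at 0.18 and 0.95. Among probes outside the chromosome tiles, the BrdU ratio on the sap1-1 array was higher by 0.63 for the mitochondrial genome (60 of 60 probes). For probes named pNSU, whose place in the genome is not given, it was higher by 0.35 (100 of 129 probes).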

How the results depend on the processing

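No paired analysis was possible because each strain has 1 array. The tests with smoothing over 2500 bp, the GC correction, Cy5 over the mean input and division by the slope were chosen after the data had been seen. The lower BrdU at the ends of chromosomes I and II kept its direction in all 11 alternatives run on it, between -1.62 and -0.66, and so did each of the 4 ends taken alone. Of the values that answer a comparison, 190 stayed within their tile scatter or within 1.5 times the count, 103 moved and 1 changed sign from an interval that left out 0. Of the values of single classes, regions and loci, 524 stayed, 136 moved and 5 changed sign in that way. Counted from any main value, also those near 0, the sign changed in 3 of 62 differences of the first kind, all at the ends of chromosome III, and in 42 of 659 of the second. The filter on dim tiles moved none of the values that answer a comparison, as it left out very few tiles. Signal over background limits few tiles, but the scatter of single tiles limits short regions, since of simulated regions lowered by 1.5 log2 those of 7 tiles were called in 70.0% and those of 20 tiles in 100%, while of unchanged ones of 7 tiles 85.0% were called and stayed under 2-fold. Counts with stricter or looser thresholds change by construction. For the other changed values below, the cause was not tested. Both ends of chromosome III changed sign with centring on the mode and the left also over 50 kb, coding tiles and arms with quantile scaling, intergenic tiles with loess and with division by the slope, and the pericentromere of chromosome II with that division.

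A 3-fold region threshold gave 394 regions in sap1-1, 71.2% of wild-type regions shared, 79.4% of sap1-1 regions shared and 25 regions higher. A 3-fold region threshold also gave a median height of 2.34 in wild-type, a median height of 2.39 in sap1-1 and a profile width of 7.5 kb in sap1-1. A region threshold at the percentile 90 of each array gave 410 regions in sap1-1, 67.1% of sap1-1 regions shared, 27 regions higher and a median height of 2.45 in wild-type. A region threshold at the percentile 90 of each array also gave a median height of 2.36 in sap1-1 and a profile width of 8.7 kb in sap1-1. A minimum of 5 tiles per region gave 310 regions in wild-type, 403 regions in sap1-1, 80.1% of sap1-1 regions shared and 24 regions lower. A minimum of 5 tiles per region also gave 22 regions higher, a median height of 2.29 in wild-type, a median height of 2.25 in sap1-1 and a median length of 5.7 kb in wild-type. A minimum of 5 tiles per region further gave a median length of 3.0 kb in sap1-1 and a profile width of 6.6 kb in sap1-1. Centring on the mode gave 56.1% of wild-type regions shared, 95.4% of sap1-1 regions shared, 223 regions lower and 7 regions higher. Centring on the mode also gave a profile width of 2.4 kb in wild-type, a difference of -1.62 at the ends of chromosomes I and II, a difference of -0.54 at the left end of chromosome III and a difference of -0.54 at the right end of chromosome III. Centring on the mode further gave a difference of -1.63 at the rDNA, a difference of -1.17 at the pericentromeres and a difference of -1.23 at the mating-type region. Quantile scaling between the arrays gave 69.7% of sap1-1 regions shared, a slope of 1 across tiles, a difference of -0.80 at the rDNA and a difference of -0.39 at the pericentromeres. Quantile scaling between the arrays also gave a difference of 0.0069 at the coding tiles and a difference of 0.029 at the arms. Smoothing over 250 bp either side gave 72.4% of wild-type regions shared, a median height of 2.17 in wild-type, a median height of 2.28 in sap1-1 and a profile width of 6.3 kb in sap1-1. Wider smoothing, over 1000 bp, gave 80.7% of wild-type regions shared, 78.9% of sap1-1 regions shared, 20 regions lower and 24 regions higher. Wider smoothing also gave a median height of 1.67 in sap1-1, a median length of 6.0 kb in wild-type and a median length of 2.7 kb in sap1-1. A 1.5-fold region threshold gave 82.2% of wild-type regions shared, 70.3% of sap1-1 regions shared, 126 regions higher and a median height of 1.44 in wild-type. A 1.5-fold region threshold also gave a median height of 1.52 in sap1-1 and a profile width of 3.0 kb in wild-type. Leaving the background in gave 27 regions lower, an r of 0.763 across tiles, a slope of 1.1 across tiles and 10 tiles with higher input. Within-array loess gave 120 regions higher, a median height of 2.07 in sap1-1, a median length of 1.8 kb in wild-type and a profile width of 2.1 kb in wild-type. Within-array loess also gave a profile width of 1.8 kb in sap1-1, an r of 0.793 across tiles, a slope of 1.11 across tiles and a difference of -0.66 at the ends of chromosomes I and II. Within-array loess further gave a difference of -0.78 at the rDNA, a difference of -0.36 at the pericentromeres and a difference of 0.041 at the intergenic tiles. Background correction by normexp gave an r of 0.757 across tiles and a slope of 1.12 across tiles. Leaving out repeated sequence gave an r of 0.728 across tiles, a slope of 1.18 across tiles, a difference of -0.31 at the pericentromeres and 4 tiles with lower input. Counting differences from 1.5-fold gave 112 regions lower and 159 regions higher. Chromosome ends of 50 kb gave a difference of -0.25 at the left end of chromosome III. Smoothed values in place of single tiles gave an r of 0.804 across tiles and a slope of 1.04 across tiles.

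Smoothing over 2500 bp either side gave 225 regions in wild-type, 249 regions in sap1-1, 80.9% of wild-type regions shared and 87.6% of sap1-1 regions shared. Smoothing over 2500 bp either side also gave 12 regions lower, 2 regions higher, a median height of 1.65 in sap1-1 and a median length of 10.2 kb in wild-type. Smoothing over 2500 bp either side further gave a median length of 6.0 kb in sap1-1 and a profile width of 6.0 kb in sap1-1. Correction for GC content gave a median height of 1.78 in wild-type, a median height of 1.74 in sap1-1, a median length of 3.9 kb in wild-type and a profile width of 9.9 kb in sap1-1. Correction for GC content also gave an r of 0.708 across tiles. Cy5 over the mean input of both arrays gave 25 regions lower, a difference of -0.57 at the rDNA and a difference of -0.25 at the pericentromeres. Division of sap1-1 by the slope of the broad profiles gave 146 regions higher, a difference of -0.78 at the ends of chromosomes I and II, a difference of 0.24 at the right end of chromosome III and a difference of -1.05 at the rDNA. Division of sap1-1 by the slope of the broad profiles also gave a difference of 0.065 at the pericentromere of chromosome II, a difference of -0.031 at the pericentromeres, a difference of -0.19 at the mating-type region and a difference of 0.056 at the intergenic tiles.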

Other observations

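Most sets of probes outside the chromosome tiles had BrdU ratios above the median of the array in both strains. The 110 probes named for the mating-type region had a median ratio of 2.73 in wild-type and 2.18 in sap1-1, with 10 of them higher in sap1-1 and a median difference of -0.58. The mitochondrial probes stood at 0.50 in wild-type and 1.21 in sap1-1, with an input difference of -0.11. The pNSU probes are named after plasmid clones whose place in the genome is not given. Whether they bear on the chromosome ends was not tested. The pNSU sets together stood at 2.09 in wild-type and 2.51 in sap1-1, higher in sap1-1 unlike the tiles at the ends of chromosomes I and II. Among these sets the median difference was 0.41 for the 27 probes of pNSU21, 0.42 for the 14 of pNSU64, 0.35 for the 19 of pNSU65, 0.45 for the 9 of pNSU70, 0.11 for the 29 of pNSU71 (at 0.018 in wild-type and 0.26 in sap1-1) and 0.057 for the 24 of pNSU77. The sets of 2 or 3 probes gave 0.42 (pNSU32), 0.13 (pNSU28) and -1.07 (pNSU68, with both probes lower).

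BrdU ratios were higher where GC content was lower, with r of -0.335 in wild-type and -0.333 in sap1-1 across tiles. After removal of the running median the values were -0.495 and -0.364. Of 588 arm windows of 20 kb, 5 were 2-fold lower in sap1-1 and 0 higher, against 9 and 0 of 20 subtelomere windows.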
